A study of Mus musculus with 48 samples.

How the data were processed

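The series profiled mouse R1 embryonic stem cells grown in 2i medium with LIF, which holds the cells in a naive pluripotent state through inhibitors of MEK and GSK3. Of its 48 samples, the 9 polyadenylated RNA-seq libraries were analysed here: 3 of wild-type cells (WT), 3 of cells with both Mll3 and Mll4 knocked out (dKO) and 3 of cells with catalytically deficient Mll3 and Mll4 (dCD). The ChIP-seq, ATAC-seq, GRO-seq and Start-seq samples were not analysed here. Samples were grouped by their titles. The labels name 1 line per genotype and do not say whether replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical, and the effect of a clone cannot be separated from that of its genotype.

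The deposited table holds 1 TPM value per gene and library and a gene length in bases. Per the submitters' processing notes, the tools were HISAT2, featureCounts and DESeq2, with no versions, and the genome build was mm9; the notes give no role for each tool. The annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart. The 48321 rows carry gene symbols, of which 46417 matched the reference name tables. In 27 rows the symbol had been turned into a date, with 2 of these dates used more than once, and such rows were tested without a name. Chromosomes and the order of neighbouring genes were taken from a GRCm38 table by symbol, and no coordinates are printed because the builds differ. Of the 16179 tested genes, 14793 (91.4%) had a chromosome.

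TPM keeps no depth by itself, but every deposited value multiplied by the gene length was a whole multiple of 1 step per library, with 100% of values whole within 0.01. The recovered depth was 25911802, 40519709 and 21090624 reads for WT replicates 1 to 3. It was 25956251, 33392132 and 29456783 reads for dKO, and 36274357, 31833673 and 56249770 reads for dCD. The median tested gene held 350 to 913 reads per library, so counting error was small for most tested genes. Values near the minimum of 1 TPM rest on fewer reads and are less certain. Chi-square values per degree of freedom between replicates of a line ranged from 1.58 to 4.14, so no library was a copy of another. These values do not show whether replicates were separate cultures.

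Genes with a TPM of at least 1 in at least 3 of the 9 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend) on log2(TPM + 1), with all 9 libraries in 1 fit and 3 contrasts. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg, and the threshold was 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. Because the adjusted p alone passed most genes, the paragraph of gene counts in each contrast leads with genes that also changed at least 2-fold. List members given as higher or lower passed at the adjusted p alone, unless a 2-fold count is named. The 2-fold threshold was set beforehand as another threshold, and leading with it was decided after the data were examined. A moderated F test in the same fit asked which genes differed among the 3 lines. The remaining tables were made with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.

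The groups, the tests, the alternatives and 33 gene lists were fixed before the data were examined. Lists of chromatin and cell state covered H3K4 methyltransferase complexes, acetyltransferases and demethylases, Polycomb, general, naive and formative or primed pluripotency, and two-cell-like genes. Lists of lineages and pathways covered germline, mesoderm, endoderm, trophoblast, neural ectoderm, Hox genes, signalling targets (Nodal and TGF-beta, Wnt, MEK-ERK, retinoic acid), stress and p53, metabolism, ribosomal proteins and cell cycle. The remaining lists covered transcription elongation, DNA methylation, imprinting, interferon, extracellular matrix, fibroblast and feeder cells, the Y chromosome and the mitochondrial genome. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with p-values adjusted over 32 lists and 3 contrasts; camera with an estimated correlation and fry were alternatives. The mitochondrial list had no tested member, because the mitochondrial genes reached at most 0.77 TPM and 6 to 20 reads per library.

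Named genes were chosen by a fixed rule. After Kmt2c and Kmt2d, the 10 genes with the largest and the 10 with the smallest log2 fold change were taken per contrast, among genes past the threshold, with non-overlapping libraries and a mean of at least 1 TPM in a group. Then followed up to 4 called members per list by p-value, with both directions present where both occurred. Symbols of Gm and a number, Rik symbols and accessions were skipped, and so were clone names and date-like names, which is slightly wider than the wording fixed beforehand. Results of some single genes are not reported here.

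The procedure was tested on simulated reads with 200 changed genes. For dKO against WT, in 15623 simulated genes, it recovered 61.2% of genes with a true log2 change of 0.5, 94% at 1 and 97% at 2. For dCD against WT, in 15596 genes, the shares were 71.6%, 82.1% and 97%, and for dKO against dCD, in 15566 genes, 64.2%, 92.4% and 93.9%. Of the simulated calls, 8.7%, 7.7% and 2.4% were false, so in the contrasts against WT the false share exceeded the nominal 5%. Each contrast was simulated once, with 1 spread for all genes taken from the WT libraries. The real contrasts called 58.4% to 71.8% of genes, far more than the 200 simulated. These shares are therefore not error rates of the real calls.

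Alternatives covered other pseudocounts, filters, scalings, variance models and fits, leaving out each library, and a voom fit to the recovered reads, which was added after the data were examined. Overlaps between the mutant lines were set beside 100 simulated sets of unchanged groups, since both contrasts use the same WT libraries.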

Results

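RNA from 3 lines of mouse embryonic stem cells was compared, with 3 libraries per line: WT, dKO, in which the histone methyltransferases Mll3 (Kmt2c) and Mll4 (Kmt2d) were knocked out, and dCD, in which their catalytic activity was disabled. Depth ranged from 21090624 to 56249770 recovered reads per library. Libraries of a line correlated at r of 0.994 to 0.996 across genes and libraries of different lines at 0.940 to 0.968, where genes are not independent replicates. The first principal component held 60.2% of the variance and the second 29.9%. By limma's moderated F test, 13364 of 16179 genes (82.6%) differed among the lines at an adjusted p under 0.05.

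The targeted genes were examined first. Kmt2c measured 21.65, 19.68 and 21.93 TPM in WT and 8.0, 7.55 and 7.44 TPM in dKO, a log2 fold change of -1.35 (SE 0.0568, limma adjusted p = 8.37e-09). In dCD it measured 28.56, 25.26 and 27.04 TPM, a log2 fold change of 0.34 against WT (SE 0.0568, limma adjusted p = 0.000491). Kmt2d was not lower in dKO: it measured 67.39, 65.24 and 66.59 TPM in WT and 84.84, 80.51 and 83.48 TPM in dKO, a log2 fold change of 0.32 (limma adjusted p = 0.00194). In dCD, Kmt2d measured 67.17, 54.62 and 67.82 TPM, which did not pass the test against WT (log2 fold change -0.08, limma adjusted p = 0.368). The sign of that value rested on dCD replicate 2, without which it was 0.02 (limma adjusted p = 0.544). The labels do not give the edited part of either gene, so reads outside an edited part check nothing, and the Kmt2d values neither bear out nor contradict the labels.

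**Figure D1:**
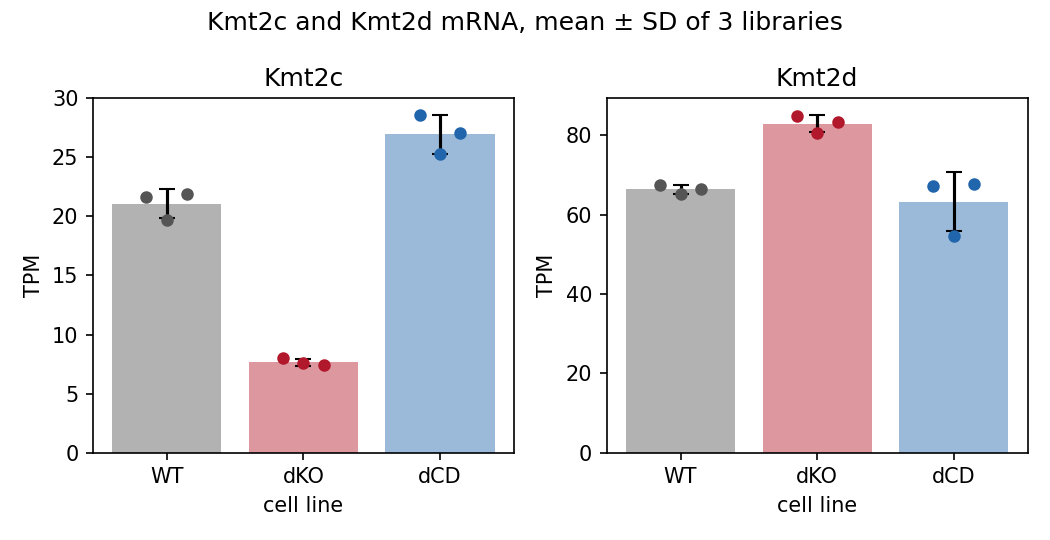
Kmt2c (left) and Kmt2d (right) mRNA in TPM for each cell line, with bars at the mean, error bars of 1 SD and points for the 3 libraries. Kmt2c lies between 7.44 and 8.0 TPM in dKO and at or above 19.68 TPM in WT, while Kmt2d lies at or above 80.51 TPM in dKO.

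The comparison of dKO with WT set the knockout line beside the unedited line. Genes of the Hox clusters, which pattern the body axis and are low in embryonic stem cells, rose: 27 of 28 tested Hox genes were higher, 25 of them at least 2-fold, and none lower. Hoxa10 went from 0.607 ± 0.0498 to 89.7 ± 2.84 TPM (SD, n = 3), a log2 fold change of 5.82 (SE 0.0692, limma adjusted p = 1.80e-12), and Hoxa9 from 0.202 ± 0.118 to 43.4 ± 1.01 TPM, a log2 fold change of 5.21. Transcripts of the smooth muscle proteins Acta2 and Tagln and of the imprinted growth factor Igf2 also rose, Acta2 from 0.488 ± 0.0495 to 100.1 ± 6.06 TPM (log2 fold change 6.09, SE 0.0505, limma adjusted p = 3.68e-13) and Igf2 from 3.83 ± 0.0269 to 171.6 ± 5.84 TPM. Dnmt3l, a cofactor of the de novo DNA methyltransferases, fell from 553.4 ± 22.6 to 4.16 ± 0.645 TPM (log2 fold change -6.75, SE 0.0711, limma adjusted p = 1.04e-12), and its neighbour Aire fell from 97.6 ± 6.85 to 1.80 ± 0.689 TPM.

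Other genes with the largest rises were Tex13, Sh3bgrl, the small heat shock protein gene Cryab, Hoxa11 and Hoxa5, with log2 fold changes of 4.31 to 4.80. Among the largest falls were Khdc3, Tcl1, Calcoco2, Nphs1, Ak7, Pou2f3, Rnf213 and Liph, with log2 fold changes of -5.14 to -4.08. Tcl1, a naive pluripotency gene on the fixed list, fell from 290.0 ± 5.85 to 7.88 ± 0.356 TPM. The epithelial cadherin Cdh1 fell from 169.3 ± 5.03 to 12.8 ± 0.373 TPM, a log2 fold change of -3.63.

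The Hox list passed the camera test (adjusted p = 7.38e-09), also with an estimated correlation (adjusted p = 0.0246). Cholesterol synthesis genes rose together, with 23 of 24 higher and none lower. Hmgcs1, an enzyme of the pathway, had a log2 fold change of 1.12 (camera adjusted p = 6.55e-07, adjusted p = 0.194 with an estimated correlation). Of 25 p53 targets 20 were higher and 2 lower, with Perp at 3.30, the cell cycle inhibitor Cdkn1a at 1.72 and Ei24 at -0.91 (camera adjusted p = 0.00307, adjusted p = 0.185 with an estimated correlation). General pluripotency genes moved down, with 12 of 15 lower and 3 higher. Lin28a was at -1.52 and Utf1 at -1.18, while Lin28b was at 2.18 (camera adjusted p = 0.00192, adjusted p = 0.194 with an estimated correlation). Of 23 naive pluripotency genes 14 were lower and 7 higher. Fbxo15 was at -2.56 and Dppa5a at -2.42, and Socs3 was at 1.29 (camera adjusted p = 0.00994, adjusted p = 0.341 with an estimated correlation). Markers of fibroblasts and feeder cells, among them Acta2 and Tagln, were higher for 10 of 14 members and lower for 3, with Col1a1 at 2.94, Fstl1 at 1.15 and Col5a1 at -0.93 (camera adjusted p = 0.0350, adjusted p = 0.358 with an estimated correlation).

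The other 26 lists did not pass the camera test (adjusted p from 0.123 to 0.973). Among all 16179 tested genes, 7021 were called higher and 4596 lower, so many called members alone do not set a list apart. Neural ectoderm genes were higher for 11 of 16 members and lower for 4, with Gbx2 at 1.52 and Tubb3 at -1.10; this list passed under median-ratio scaling (camera adjusted p = 0.0474). Of the developmental lists, primitive streak and mesoderm genes numbered 8 higher and 6 lower of 18, primitive and visceral endoderm 8 and 10 of 23, and trophoblast 12 and 6 of 20. Germline genes numbered 11 and 15 of 28, formative and primed pluripotency 9 and 7 of 20, two-cell-like genes 8 and 3 of 21, and retinoic acid targets 9 and 5 of 16. Evx1, beside the Hoxa cluster, was at 2.10, Col4a1 at -0.98, Lgals3 at -2.86, Stra8 at -3.80, Etv4 at -3.37 and Meis1 at 2.38. In the signalling lists, Nodal and TGF-beta genes numbered 13 higher and 6 lower of 22, Wnt targets 8 and 7 of 18, MEK-ERK targets 8 and 5 of 18, immediate early and heat shock genes 11 and 2 of 16, and interferon response genes 8 and 6 of 17. Cyclin D1 (Ccnd1) was at 2.29, Foxh1 at -2.36 and Oas1a at -3.80. H3K4 methyltransferase complex members numbered 12 higher and 5 lower of 17, with Wdr5 at -0.67, acetyltransferases and demethylases 3 and 5 of 12, and Polycomb 8 and 8 of 20. Transcription elongation genes numbered 9 and 5 of 23 and DNA methylation genes 5 and 5 of 11, with Dnmt3b at -1.45. Imprinted genes were higher for 19 of 29 and lower for 7, with Mest at 2.30, Peg10 at 2.51 and Rian at -1.20. Oxidative phosphorylation genes numbered 19 higher and 3 lower of 29, glycolysis 10 and 11 of 25, and integrated stress response 10 and 6 of 19. Cell cycle genes numbered 18 and 7 of 29, ribosomal proteins 13 and 10 of 38, extracellular matrix and adhesion 10 and 15 of 26, and the Y chromosome 4 and 1 of 5. Ribosomal proteins passed as lower under median-ratio scaling (camera adjusted p = 0.0257). The median, the mean and the test differed in sign for 8 of these lists, namely Polycomb, formative and primed pluripotency, mesoderm, endoderm, Wnt targets, glycolysis, ribosomal proteins and extracellular matrix. Counts adjusted over the list alone differed from those over all genes in 5 of the 32 lists, by 1 gene each.

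By limma, 2249 genes changed at least 2-fold at an adjusted p under 0.05, 972 of them higher and 1277 lower in dKO. At the adjusted p alone, 11617 genes (71.8%) passed, 7021 higher and 4596 lower (60.4% higher); after median-ratio scaling between libraries 49.9% were higher, with 5636 higher and 5650 lower. Libraries of the compared lines did not overlap for 74.4% of genes, where chance gives 10%. Among chromosomes 1 to 19 and X, chromosome 13 had the largest shift. The median log2 fold change of its 573 genes lay 0.11 above that of the other genes (0.11, 0.10 and 0.09 in the 3 dKO libraries). None of these chromosomes moved by a step of the size a gained copy gives. The Y chromosome was not examined in this way. Its 5 tested list members had a median log2 fold change of 0.78, with 4 higher and 1 lower, and a change in its copies was not tested.

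The comparison of dCD with WT set the catalytically deficient line beside the unedited line. The smooth muscle transcripts Acta2 and Tagln rose more than any other named gene, Acta2 from 0.488 ± 0.0495 to 520 ± 24.9 TPM (SD, n = 3; log2 fold change 8.45, SE 0.0505, limma adjusted p = 4.40e-14) and Tagln from 2.38 ± 0.546 to 467.6 ± 18.8 TPM (log2 fold change 7.13). The skeletal actin gene Acta1, the secreted matrix genes Thbs1 and Tnc, the homeobox genes Rhox6 and Rhox9, Zfp36l3 and the keratin gene Krt18 rose by log2 fold changes of 4.29 to 5.99. H19, an imprinted noncoding RNA, rose from 11.01 ± 1.10 to 298.3 ± 9.11 TPM (log2 fold change 4.64, SE 0.0701, limma adjusted p = 3.25e-11). The largest falls were smaller: Myo1f went from 26.6 ± 1.09 to 3.09 ± 0.148 TPM (log2 fold change -2.75), and Aurkc, Aass, H2-Eb1, the secreted Wnt inhibitor Notum, Ushbp1, Oas1a, Acap1, Cobl and Islr2 had log2 fold changes of -2.62 to -2.28.

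Two-cell-like genes, a set that peaks in the early mouse embryo and in rare embryonic stem cells, were higher for 18 of 21 members and lower for 2, with 17 higher at least 2-fold. Usp17le was at 3.23, Zscan4d at 3.08 and Zscan4a at 2.97, while Pramel7 was at -1.56. This list passed camera (adjusted p = 8.77e-07) also with an estimated correlation (adjusted p = 0.0247). The Zscan4 genes are near-identical copies, so the value of a single copy is uncertain. Naive pluripotency genes were lower for 19 of 23 and higher for 2, none by 2-fold, with Nr0b1 at -0.93, Esrrb at -0.81 and Zfp42 at -0.55 (camera adjusted p = 2.33e-06, adjusted p = 0.173 with an estimated correlation). General pluripotency genes were lower for 9 of 15 and higher for 2, with Sox2 at -0.75 (camera adjusted p = 0.0159, adjusted p = 0.278 with an estimated correlation). Of 20 trophoblast genes 15 were higher and 5 lower, with Rhox9 at 4.33, Krt18 at 4.29 and Cdh3 at -1.47 (camera adjusted p = 0.000145, adjusted p = 0.220 with an estimated correlation). Markers of fibroblasts and feeder cells were higher for 10 of 14 and lower for 2, with Acta2 and Tagln as given and Col5a2 at 3.62 (camera adjusted p = 0.000145, adjusted p = 0.187 with an estimated correlation).

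Retinoic acid targets were higher for 14 of 16 and lower for none, with Nr2f2 at 1.97 and Nr2f1 at 1.26 (camera adjusted p = 0.000176, adjusted p = 0.0815 with an estimated correlation). Immediate early and heat shock genes were higher for 10 of 16 and lower for 1, with Jun at 2.52 and Fos at 1.41 (camera adjusted p = 0.00160, adjusted p = 0.104 with an estimated correlation). Primitive and visceral endoderm genes were higher for 14 of 23 and lower for 5, with Lrp2 at 2.14, Col4a2 at 1.77 and Lama1 at -1.26 (camera adjusted p = 0.00432, adjusted p = 0.278 with an estimated correlation). Extracellular matrix and adhesion genes were higher for 15 of 26 and lower for 8, with Col1a2 at 2.87 and Vim at -0.33 (camera adjusted p = 0.0201, adjusted p = 0.519 with an estimated correlation). Germline genes were higher for 18 of 28 and lower for 7, with Sycp3 at 1.71 and Stag3 at -0.66 (camera adjusted p = 0.0350, adjusted p = 0.508 with an estimated correlation). Neural ectoderm genes were higher for 10 of 16 and lower for 3, with Irx3 at 2.06 and En2 at -0.95 (camera adjusted p = 0.0480, adjusted p = 0.220 with an estimated correlation).

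In the other 21 lists, camera did not pass (adjusted p from 0.0717 to 0.973). For comparison, 4683 of all 16179 tested genes were called higher and 4770 lower. Hox genes were higher for 13 of 28 and lower for 2, and p53 targets were higher for 14 of 25 and lower for 6, with Plk2 at 1.35. Cholesterol synthesis genes numbered 11 higher and 5 lower of 24, imprinted genes 14 and 10 of 29, with Igf2 at 3.89, and MEK-ERK targets 5 and 10 of 18, with Spry4 at -1.88. Formative and primed pluripotency genes numbered 11 and 6 of 20, with Otx2 at 1.51, and mesoderm 7 and 3 of 18. Nodal and TGF-beta genes numbered 8 and 10 of 22, Wnt targets 8 and 6 of 18, with Dkk1 at 3.01, and interferon response genes 7 and 5 of 17. Chromatin lists numbered 5 higher and 5 lower of 17 for H3K4 methyltransferase complexes, 1 and 5 of 12 for acetyltransferases and demethylases, 10 and 6 of 20 for Polycomb and 3 and 6 of 11 for DNA methylation, with Dnmt3l at -0.84. Glycolysis genes numbered 8 and 9 of 25, oxidative phosphorylation 9 and 6 of 29, and integrated stress response 9 and 6 of 19. Cell cycle genes numbered 9 and 11 of 29, ribosomal proteins 10 and 3 of 38, transcription elongation 6 and 7 of 23 and the Y chromosome 3 and 1 of 5. The median, the mean and the test differed in sign for Nodal and TGF-beta, integrated stress response and cell cycle genes. Called members adjusted over the list alone differed from those over all genes in 11 lists, by at most 2 genes.

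By limma, 1123 genes changed at least 2-fold, 747 higher and 376 lower in dCD. This count depended on the processing, with 1744 genes at a pseudocount of 0.1, 1854 with voom on recovered reads and 695 at a minimum of 5 TPM. Medians of lists with low genes depended on it too. The Hox median of 0.23 in dCD was 0.02 under quantile normalization and 0.72 with voom, and that of 2.16 in dKO was 3.85 with voom. The two-cell-like medians of 1.83 in dCD and 0.28 in dKO were 3.42 and 0.59 with voom. In all, 9453 (58.4%) passed at the adjusted p alone, 4683 higher and 4770 lower. Among chromosomes 1 to 19 and X, the X chromosome had the largest shift, 0.08 above the other genes over 544 genes. The 5 tested members of the Y chromosome list had a median log2 fold change of 0.39, with 3 higher and 1 lower.

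**Figure D2:**
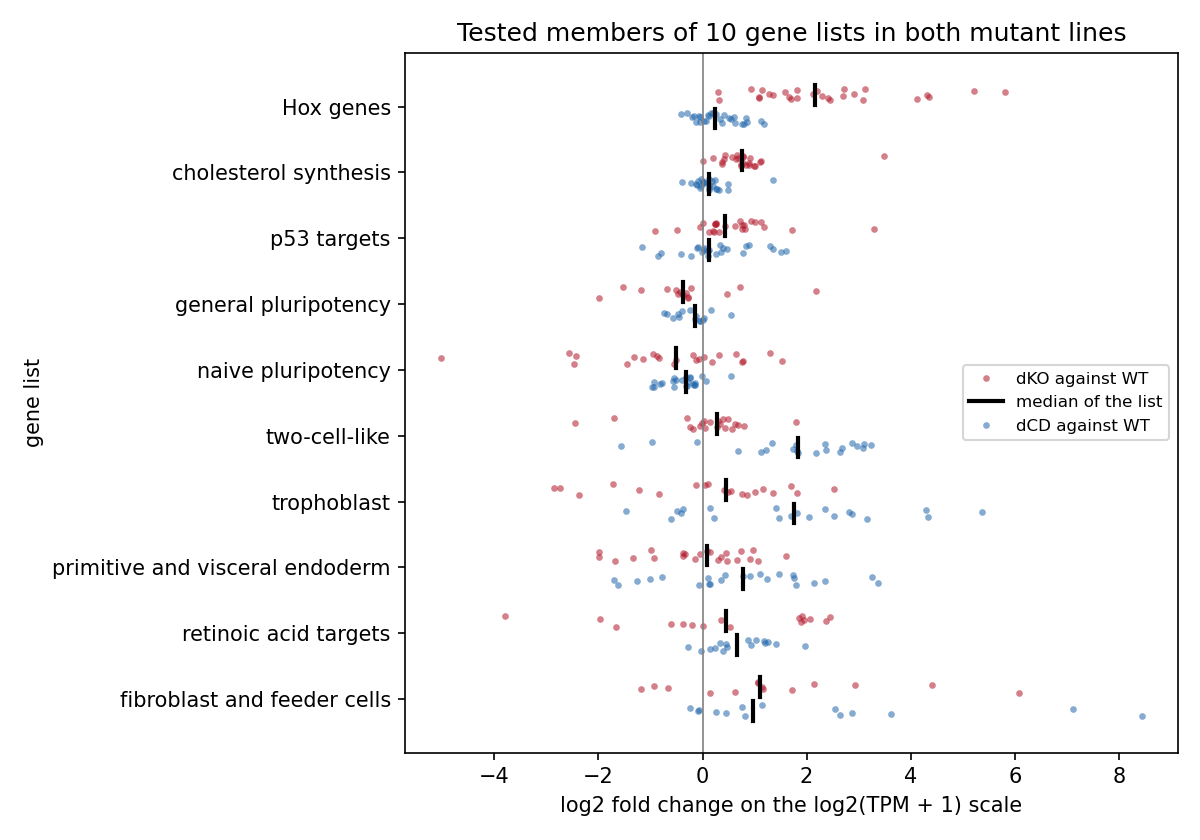
Each point is a tested member of a gene list, placed by its log2 fold change on the log2(TPM + 1) scale in dKO (red) or dCD (blue) against WT, and black bars mark list medians. The Hox median is 2.16 in dKO and 0.23 in dCD, and the two-cell-like median is 0.28 in dKO and 1.83 in dCD.

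Both contrasts used the same WT libraries. At least 2-fold, 265 genes were higher in both mutant lines and 248 lower in both, where independent lists would share 44.9 and 29.7. The shared genes were 27.3% of the higher and 19.4% of the lower 2-fold genes of dKO. In the direct contrast with dCD, 80% and 90.4% of those dKO genes also differed in the same direction at an adjusted p under 0.05. That contrast uses the same dKO libraries and passed 69.3% of all tested genes, counting both directions. Of all 16179 tested genes, 6846 were higher and 4374 lower in it. The 513 shared genes became 963 with a pseudocount of 0.1. Acta2, Tagln, Igf2 and Thbs1 were among those higher in both, and Oas1a was among those lower in both. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.488. Simulated unchanged groups gave 0.499, since the same WT libraries enter both contrasts, so r alone does not show a shared change. The covariance was 0.211 against a simulated mean of 0.00649 and at most 0.00735. Spread between the shared WT libraries is thus argued against as the whole source of the covariance. A deviation of the WT line itself would also enter both contrasts and was not simulated. How many of the shared genes owe their call to the shared controls was not measured.

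**Figure D3:**
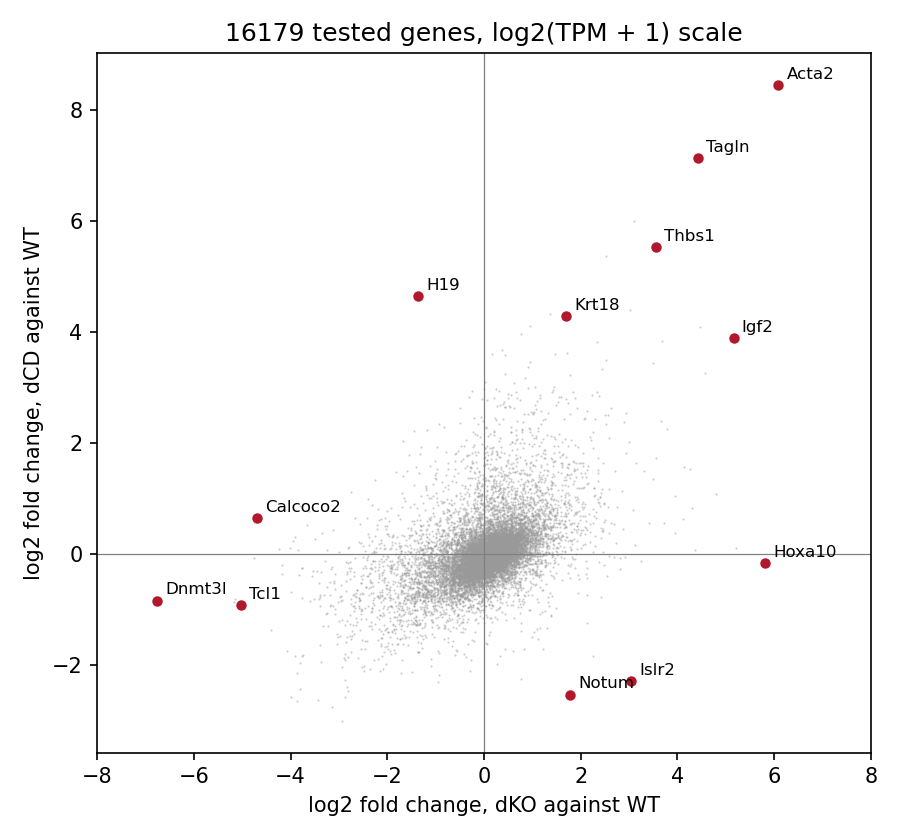
Each grey point is 1 of 16179 tested genes, with its log2 fold change in dKO (horizontal axis) and dCD (vertical axis) against WT, and 12 named genes are marked in red. Acta2 lies at 6.09 and 8.45, Hoxa10 at 5.82 and -0.16, and H19 at -1.37 and 4.64.

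The direct comparison of dKO with dCD tested the difference between these lines, with 1 line per genotype. Hoxa genes were higher in dKO than in dCD, with Hoxa10 at a log2 fold change of 5.98 (SE 0.0692, limma adjusted p = 1.92e-12) and Hoxa9, Hoxa11, Hoxa7 and Hoxa5 at 3.48 to 5.09. Islr2 and Notum were higher in dKO, Islr2 at 157.7 ± 3.89 against 2.96 ± 0.0534 TPM (SD, n = 3) and Notum at 153.1 ± 3.55 against 6.79 ± 0.277 TPM. Notumos, named as the antisense partner of Notum, moved with it at 4.10 and cannot be separated from it without a strand setting, while Tex13 and the neural transcription factor Olig3 were at 3.72 and 3.57. H19 was lower in dKO, at 3.65 ± 0.343 against 298.3 ± 9.11 TPM (log2 fold change -6.01, SE 0.0701, limma adjusted p = 1.94e-12). Dnmt3l was at -5.91, Calcoco2 at -5.34, Stra8 at -4.66 and Cdh1 at -4.40, and Ak7, Khdc3, Aire, Myh13 and Cidea lay between -4.35 and -4.18.

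All 21 tested two-cell-like genes were lower in dKO than in dCD, 16 at least 2-fold, with Tmem92 at -3.07 (camera adjusted p = 6.16e-09, adjusted p = 0.0246 with an estimated correlation). Hox genes were higher for 25 of 28 and lower for 1, Hoxb4 at -0.44 (camera adjusted p = 5.94e-08, adjusted p = 0.0246 with an estimated correlation). Cholesterol synthesis genes were higher in dKO for 24 of 24, with Cyp51 at 0.86 (camera adjusted p = 2.30e-07, adjusted p = 0.194 with an estimated correlation). Of 20 trophoblast genes 19 were lower and 1 higher, with Krt18 at -2.60, Krt8 at -2.31 and Tead4 at 0.41 (camera adjusted p = 6.16e-09, adjusted p = 0.103 with an estimated correlation). Extracellular matrix and adhesion genes were lower for 18 of 26 and higher for 6, with Cldn4 at -2.47 and Mmp14 at 1.59 (camera adjusted p = 0.000146, adjusted p = 0.331 with an estimated correlation). Primitive and visceral endoderm genes were lower for 14 of 23 and higher for 5, with Sparc at -2.78 and Apoe at 0.41 (camera adjusted p = 0.00135, adjusted p = 0.220 with an estimated correlation). Germline genes were lower for 16 of 28 and higher for 8, with Rpl10l at -2.51 (camera adjusted p = 0.00571, adjusted p = 0.358 with an estimated correlation). Fibroblast and feeder cell markers were lower for 9 of 14 and higher for 4, with Tagln at -2.71, Acta2 at -2.37 and Loxl1 at 2.38 (camera adjusted p = 0.0273, adjusted p = 0.341 with an estimated correlation); under median-ratio scaling this list did not pass (camera adjusted p = 0.0902).

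The other 24 lists did not pass camera (adjusted p from 0.0514 to 0.973). For comparison, 6846 of all 16179 tested genes were called higher and 4374 lower. Cell cycle genes numbered 20 higher and 5 lower of 29, with Cdkn2a at 1.09, p53 targets 16 and 5 of 25, with Perp at 1.80, and oxidative phosphorylation genes 17 and 2 of 29. General pluripotency genes numbered 7 and 7 of 15, naive pluripotency 9 and 10 of 23, with Fbxo15 at -3.10, formative and primed pluripotency 6 and 9 of 20, and mesoderm 6 and 10 of 18. Neural ectoderm genes numbered 8 and 7 of 16 and retinoic acid targets 6 and 6 of 16. Nodal and TGF-beta genes numbered 13 and 7 of 22, with Inhbb at 2.55, Wnt targets 6 and 9 of 18, and MEK-ERK targets 11 and 5 of 18. Immediate early and heat shock genes numbered 6 and 9 of 16 and interferon response genes 7 and 7 of 17. H3K4 methyltransferase complexes numbered 10 and 5 of 17, acetyltransferases and demethylases 7 and 4 of 12, Polycomb 8 and 10 of 20, with Aebp2 at -0.96, DNA methylation 7 and 3 of 11 and transcription elongation 8 and 9 of 23. Imprinted genes numbered 14 and 12 of 29, with Ndn at 1.59, glycolysis 10 and 10 of 25, integrated stress response 11 and 7 of 19, with Cth at -2.71, ribosomal proteins 7 and 14 of 38 and the Y chromosome 2 and 1 of 5. Ribosomal proteins passed as lower under median-ratio scaling (camera adjusted p = 0.00137). Signs of the median, the mean and the test differed for 6 lists, namely acetyltransferases and demethylases, naive pluripotency, integrated stress response, glycolysis, DNA methylation and imprinted genes. Numbers adjusted over the list alone differed from those over all genes in 4 lists, by at most 2 genes.

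By limma, 1774 genes differed at least 2-fold between the mutant lines, 583 higher and 1191 lower in dKO, or 2710 with voom on recovered reads, and 11220 (69.3%) passed at the adjusted p alone. Of the latter, 61.0% were higher in dKO and 48.9% after median-ratio scaling. Chromosome 13 again had the largest shift among chromosomes 1 to 19 and X, 0.08 above the other genes.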

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

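Tests of the contractile and two-cell-like patterns were chosen after the results were seen; the scaling and length tests were fixed before their values were seen. Of 44 genes called at least 2-fold against WT in opposite directions in the mutant lines, 4 were named genes whose dKO and dCD effects differed by limma's direct contrast. The 44 were fewer than independent lists would give: 13 higher and 31 lower in dKO, against 22.6 and 59, and the shared WT libraries also lower such counts. H19 differed by -6.01, with -1.37 in dKO and 4.64 in dCD. Islr2 differed by 5.32, with 3.04 in dKO and -2.28 in dCD. Notum differed by 4.31, with 1.77 and -2.53. Notumos differed by 4.10, with 2.26 and -1.84, and its reads cannot be told apart from those of Notum. Outlying libraries were not tested for; in dCD, Kmt2d measured 54.62 TPM in replicate 2 against 67.17 and 67.82 TPM, and leaving that library out gave 8717 calls against WT in place of 9453.

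More genes passed the test higher than lower in dKO against WT at the adjusted p alone. Among genes changed at least 2-fold the balance was the other way, with 972 higher and 1277 lower. The share of higher calls stayed above even in each of 3 equal classes of genes by length. It rose with length, from 53.8% in the shortest class to 65.0% in the longest. The even mark itself depends on the library scaling, so these shares cannot decide on gene length as the whole cause. Library scaling cannot be told apart from a wide rise in dKO: median-ratio scaling gave 49.9% higher, but it centres the median gene and so fixes this outcome, while quantile normalization gave 56.7%, TPM rescaled without the 20 most abundant genes 59.2% and voom on recovered reads 57.8%. The values hold no external standard, and a biological rise stays open and untested.

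Acta2 and Tagln rose in both mutant lines. Fibroblasts or feeder cells would bring all their abundant transcripts, yet Acta2 was 605 times in dCD and 160 times in dKO the median TPM of Col1a1, Col1a2, Col3a1, Dcn, Lum and Postn, which argues against such cells as the whole source. The median of those 6 transcripts still went from 0.0221 TPM in WT to 0.628 in dKO and 0.859 in dCD. Col1a1 was at 10.2 TPM beside Acta2 at 100.1 TPM in dKO. The 6 were picked after the results were seen, from the fibroblast and feeder list, which also holds Acta2 and Tagln. Of its 14 tested members, 10 were higher in each mutant line, with 3 lower in dKO and 2 in dCD. A small share of such cells therefore stays open. Of 16 other contractile and serum-response-factor targets, all were higher in dCD (median log2 fold change 1.81, MAD 1.37), while in dKO the median was 0.69 (MAD 0.77) and Myh9 (-1.29) and Actn1 (-0.85) were lower. A wider contractile programme may therefore account for the pattern in dCD and for part of it in dKO, as a hypothesis found and tested on the same data, and a difference between clones was not tested.

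Two-cell-like genes rose in dCD. Reads moving between near-identical copies would leave the family total level, but summed Zscan4 reads, divided by library depth, were 11.6 times higher in dCD than in WT, with no overlap of libraries. A single deviating library is argued against as well, since the list summed to 228 TPM in the lowest dCD library and to at most 91.5 TPM in WT. A larger share of two-cell-like cells or a higher level per cell may underlie the pattern, and bulk RNA does not separate them. A difference between clones stays open and untested.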

How the results depend on the processing

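All leave-one-out counts stayed within 1.5 times the main count. At an adjusted p under 0.05 they ranged from 11084 to 11672 genes for dKO against WT, 8717 to 9382 for dCD against WT and 10620 to 11259 for dKO against dCD. At 2-fold they ranged from 2241 to 2264, 1122 to 1140 and 1775 to 1813, among the 3 lines from 13013 to 13178, and for shared calls from 5462 to 5733, or 507 to 529 at 2-fold. Requiring 2-fold left 2249, 1123 and 1774 genes, since it is stricter. The settings for 2-fold counts and the voom fit were chosen after the data were examined. With a pseudocount of 0.1, the 2-fold count of dCD against WT was 1744 and shared 2-fold calls were 963, because a smaller pseudocount widens the fold changes of low genes. A minimum of 5 TPM, which tests fewer genes, gave 695 for dCD against WT, and voom on recovered reads gave 1854, and 2710 for dKO against dCD; the cause was not tested. The replicate numbers did not pair the libraries: same-number correlations of deviations ranged from -0.05 to 0.04, and 4 of 18 were the best of their line. With the replicate block, 11533, 9273 and 11114 genes passed in the 3 contrasts, 2248, 1123 and 1774 at 2-fold. Camera called 25 list and contrast pairs, 4 with an estimated correlation and 74 by fry, which asks another question. Over the list tests in other settings, 310 kept their side of the threshold, 45 gained a call and 22 lost one. By fry, lists not called by camera moved the other way: in dKO against WT mesoderm (adjusted p = 1.79e-05), Wnt targets (2.83e-06) and integrated stress response (0.0352), and in dKO against dCD these lists (0.0114, 2.57e-06, 0.0034) and DNA methylation (1.12e-05); the cause was not tested. The chromosome 13 shift was 0.097 in dKO against WT and 0.073 against dCD with a minimum of 5 TPM. Among named genes, no called direction changed under any setting run; Kmt2d in dCD against WT, which did not pass, went from -0.08 to 0.02 without dCD replicate 2. Calls were lost for Rplp1 (dCD against WT, quantile normalization), Rps20 (dKO against dCD, median-ratio scaling) and Zfy1 (dKO against dCD), which lost its call under quantile normalization and without dKO replicate 1, dCD replicate 1 or dCD replicate 3. Depth limits low genes most.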

Other observations

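The tests of both gene lists in the first paragraph were chosen after the top genes were seen; the tests of neighbouring genes and of other splits were written before their results were seen. Contractile and serum-response-factor targets, 16 genes without those already named, were higher for 13 members and lower for 2 in dKO and higher for all 16 in dCD by limma. In dCD, Myl9, a myosin light chain, was at a log2 fold change of 3.33, calponin (Cnn1) at 2.92 and Tpm1 at 2.52. In dKO, Myl9 was at 2.44, but the nonmuscle myosin gene Myh9 was at -1.29 and the alpha-actinin gene Actn1 at -0.85. YAP targets went separate ways: in dCD 8 of 10 were higher and none lower, with Cyr61 at 2.81 and Ctgf at 1.85, while in dKO 5 were higher and 5 lower, with Amotl2 at -0.88. All 10 YAP targets were lower in dKO than in dCD.

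Neighbouring genes changed together more often than shuffled gene orders gave. In dKO against WT, 359 pairs of adjacent tested genes were called at least 2-fold in the same direction, where 1000 shuffles within chromosomes gave a mean of 149.4 and at most 185. In dCD against WT there were 152 such pairs, with a shuffled mean of 42.5 and at most 63. Pairs whose symbols share no stem numbered 278 and 99, above shuffled highs of 174 and 58. The stem was the part of a symbol before its first digit, so related genes with unlike names still counted there. In dCD the longest run held 12 genes with Gm symbols, and another held the 6 Zscan4 genes, which are near-identical copies. How reads with several matches were treated is not given. A run of neighbours higher in dKO held 9 genes from Hoxc13 to Hoxc4. Smaller runs held Acta2, Fas, Lipa and Ifit2, which rose, and Aire, Dnmt3l and Icosl, which fell. A candidate explanation is regulation shared over a region; reads of overlapping genes counted for both could also add pairs, and the strand setting is not stated.

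Other splits of the libraries were counted. The 6 libraries of a pair of lines make 10 splits, too few for a share under 0.05. In each contrast 1 split, the real one, gave as many calls. For dKO against WT the real split gave 11617 calls and 2249 at 2-fold, and the highest other gave 0. For dCD against WT it gave 9453 and 1123, with 0 as the highest other, and for dKO against dCD 11220 and 1774, with 1 as the highest other. For the F test over 9 libraries, 1 of 100 of the 280 possible splits, the real one with 13364 genes, gave as many. The highest other gave 7041, so libraries of a line resembled each other more than those of other lines. Splits that mix lines add the difference between lines to the spread within groups. The counts therefore cannot exclude a difference between clones or cultures.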
